A study of Triticum polonicum with 8 samples.

How the data were processed

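The tables hold RNA sequencing of roots of dwarf Polish wheat seedlings, a tetraploid wheat whose nuclear genome consists of the A and B subgenomes. Per the labels, roots were sampled at an age of 4 weeks after 1 week of treatment. The design crosses 2 levels each of Ca/K supply, Cd and Zn, giving 8 treatments. N0 denotes the basal supply of 4 mM calcium nitrate and 5 mM potassium nitrate, and N2 denotes 8 mM and 10 mM. Cd treatment was 80 µM CdCl2 and Zn treatment was 500 µM Zn, on a basal medium with 5 µM Zn. Because both salts are nitrates, the nitrate supply computed from these doses was 13 mM in N0 and 26 mM in N2, so Ca, K and nitrate were raised together.

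Per the labels' protocols, total root RNA was extracted with Trizol and made into libraries with an Illumina TruSeq kit, while the series design text names a long-read method; the platform behind these tables is therefore taken from the protocols only. The submitters' processing notes name Bowtie2 2.0.6 and TopHat2 2.0.12. The counting tool, its strand setting and its treatment of reads shared between near-identical copies, the genome build and the annotation release are not given in the sources used here beyond the gene identifiers. Those with an arm code name TGACv1 gene models of Chinese Spring, a hexaploid bread wheat with a D subgenome. The deposited counts are whole numbers of reads per gene, with 1 column per treatment. The labels state 3 biological replicates per treatment, and whether their RNA or reads were pooled into the 1 column is not given in the sources used here. The deposited FPKM values, made by the authors, equal the count divided by gene length and column total, with whole-number lengths recovered to a relative deviation of 2.3e-14 at most, so that this table adds only gene lengths (median 1706 bp) to the counts. Each of the 16 columns was matched to its treatment by name, and 0 columns were left out.

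The gene identifiers either carry a chromosome arm code (for example 7AL for the long arm of chromosome 7A, U where no arm is given) or consist of a serial number without a position. The files do not pair the identifiers with gene names or descriptions, and no annotation was used. The 28 gene lists fixed by words in product descriptions were therefore not tested, and no list test was run. Near-identical copies on the A and B subgenomes can share reads, so the value of any single gene is uncertain to that extent. The subgenome and arm of each gene were read from its identifier. Of 124856 genes, 35769 carried an A code, 38535 a B code, 35422 a D code and 4702 the code U, and 10428 had a serial number only.

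Counts were analysed with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood fit and test with robust moderation). The additive model held Ca/K, Cd and Zn and left 4 residual degrees of freedom among the 8 libraries. Each 2-way interaction was added to it in turn, leaving 3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. In this design the residual spread contains the remaining interactions as well as noise, and p-values measure the recurrence of a change over libraries of different treatments, not the spread of replicates. The models were tested on simulated data drawn from the real means and library sizes of 64580 genes, with the dispersions fitted by the additive model. For the Cd effect, 7 of 100 genes changed 4-fold and 69 of 100 changed 16-fold were called, with 10 other genes called. For the Cd by Zn interaction, 0 of 100 and 0 of 100 were called. With the dispersion set to 0.05, all 100 of both sizes were called for the Cd effect, and 54 and 100 for the interaction.

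Pairwise comparisons set 1 library against 1 library, so they have no replicate check and no p-value. They are log2 ratios of TMM-scaled CPM (counts scaled to a common library total) with a prior count of 2, and genes with at least 5 CPM in 1 of the 2 libraries were described as 2-fold or more apart. The same rule for named genes applied to all 14 pairwise comparisons: the genes with the largest ratios in each direction among those with at least 20 CPM in 1 of the 2 libraries, of which the first 2 are printed because identifiers lack names. For tested effects the rule took called genes with the same sign in all 4 matched pairs and a mean of at least 1 CPM. A fold against a library with 0 counts is a lower bound against a floor of 3 counts in that library. Folds with few counts carry an exact 95% interval from the binomial split of the 2 counts. Such intervals and floors cover counting error only. Library totals ran from 20000875 to 25241789 counts, so that the floor of 3 counts corresponded to between 0.119 and 0.150 CPM.

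The tests, comparisons, thresholds and rule for named genes above were chosen before the data were examined. The alternatives fixed then were median-of-ratios size factors, no low-count filter, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with at least 1 FPKM in 1 library, leaving out each library in turn, and the Cd by Zn term in the additive model. For pairwise comparisons they were size factors, a prior count of 0.5, a minimum of 1 CPM, and log2(FPKM + 1). The FPKM values carry no TMM scaling, so that alternative also shifts the ratios between libraries. A replicate block was not run because the columns carry no replicate numbers. Added after seeing the data were the recurrence of 2-fold changes over the 4 matched pairs of each factor, gene sets fixed at 1 Ca/K level and read at the other, and genes with a response to Zn or Cd alone. The latter changed 4-fold or more with 1 metal in both its pairs at high Ca/K. Genes 2-fold or more apart in the same direction with the other metal alone were left out of them. These additions used the 51428 genes with a mean of at least 1 CPM. The 4 matched pairs of a factor have no library in common. The median of a set was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. For Zn-lower genes in the basal Cd library, lists that pass the same filter on the Cd ratio at high Ca/K were drawn as well. Splits of the 8 libraries into 4 and 4 were refitted in the same models, with 33 splits for each factor and 32 for each interaction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.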

Results

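Transcript levels were measured in roots of dwarf Polish wheat under 8 treatments, formed by crossing basal (N0) or raised (N2) calcium and potassium nitrate with no added metal, Cd, Zn or both metals. The series title names the question as how Ca and K go with the interaction of Cd and Zn in seedlings. Each treatment is represented by 1 library, so that no difference between single libraries has a replicate check. Totals were 24184415 counts in N0, 24999115 in N0_Cd, 25241789 in N0_Zn, 21518150 in N0_Cd_Zn, 24930243 in N2, 21745669 in N2_Cd, 21836143 in N2_Zn and 20000875 in N2_Cd_Zn. Between 73321 genes (N0_Zn) and 80499 genes (N2) had at least 1 read.

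Reads fell almost evenly on the A and B subgenomes. Genes with an A code held between 43.0% and 43.9% of the counts of a library and genes with a B code between 43.0% and 43.9%. Genes with a D code, a subgenome of bread wheat that tetraploid wheat lacks, held between 1.91% (N0; 95% Wilson interval 1.90% to 1.91%) and 2.24% (N2_Cd; 2.23% to 2.24%), and the source of these reads was not tested. N2_Cd had reads on 13525 D genes, against 10014 to 11647 in the other 7 libraries. In N2_Cd, 132 genes had at least 10 reads and no read in any other library, 77 of them with a D code, against 0 to 21 such genes in each of the other libraries.

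The basal library with both metals, N0_Cd_Zn, stood nearest to the libraries without added metal. Across 51428 genes, which are not independent replicates, its log2 CPM correlated with N0 at Pearson r = 0.84 (Spearman rho = 0.85) and with N2 at r = 0.83 (rho = 0.85), but with N0_Cd at r = 0.72 (rho = 0.76) and with N0_Zn at r = 0.69 (rho = 0.71). At high Ca/K the library with both metals instead stood nearest to N2_Zn (r = 0.91, rho = 0.92). The first principal component held 36.4% of the variance and the second 32.1%.

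**Figure D1:**
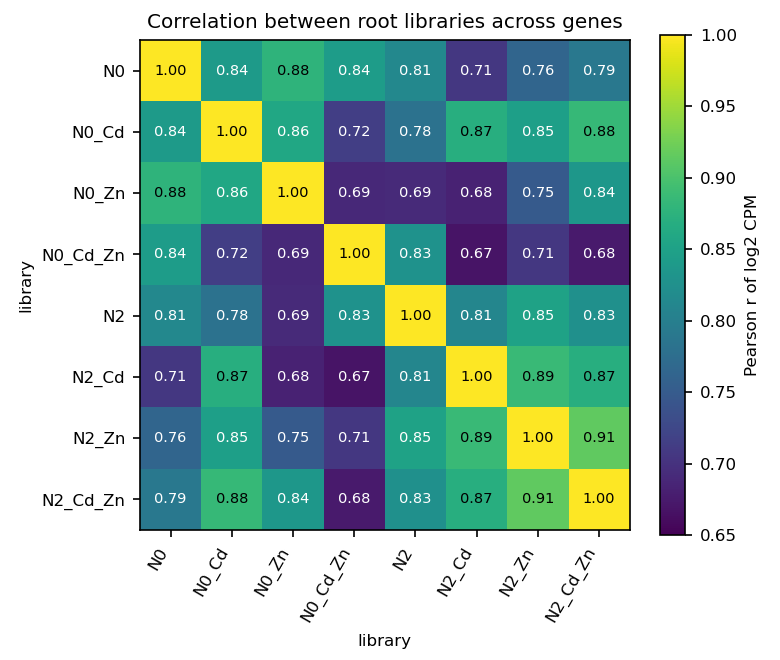
Pearson correlation of log2 CPM between the 8 root libraries (both axes), across 51428 genes; colour and printed value give r. N0_Cd_Zn has r = 0.84 with N0 and 0.69 with N0_Zn, whereas N2_Cd_Zn has r = 0.91 with N2_Zn.

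**Figure D2:**
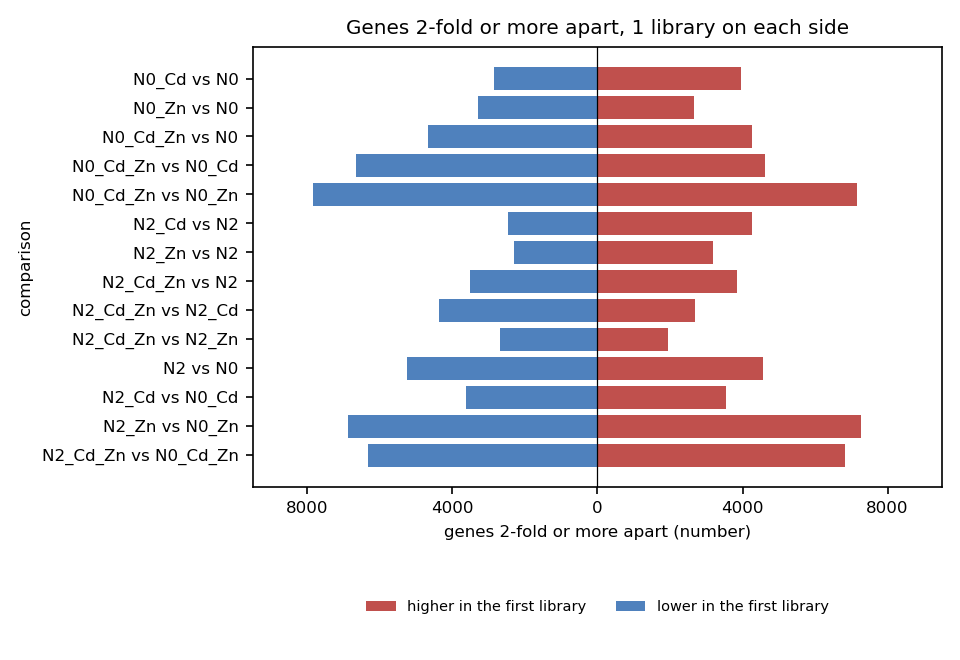
Number of genes 2-fold or more higher (right) or lower (left) in the first library of each of the 14 comparisons, 1 library on each side. N0_Cd_Zn against N0_Zn is the widest with 7166 higher and 7841 lower genes, and N2_Cd_Zn against N2_Zn the narrowest with 1943 and 2690.

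Cd at basal Ca/K went with more genes higher than lower. In N0_Cd against N0, 3950 genes were 2-fold or more higher and 2852 lower of 32686 genes compared. The A and B subgenomes contributed alike, with 1693 and 1792 genes higher and 1123 and 1057 lower. Genes with a serial number only went the other way, with 227 higher and 518 lower. The highest ratios belonged to TRIAE_CS42_4BS_TGACv1_328762_AA1093280 on chromosome arm 4BS, with 3488 counts against 3 (1096-fold, 95% counting interval 375 to 5319), and to TRIAE_CS42_1DS_TGACv1_080112_AA0239670 with a D code, with 2954 counts against 8 (348-fold, 177 to 807). The lowest belonged to TRIAE_CS42_6AL_TGACv1_472642_AA1524320, with 0 counts against 2037 (at least 720-fold lower), and TRIAE_CS42_7AL_TGACv1_559593_AA1800230, with 1 count against 2836 (3007-fold lower, interval 539 to 118800).

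The same metal at high Ca/K gave a like balance. In N2_Cd against N2, 4258 genes were higher and 2464 lower of 33269, with 1852 A genes and 1892 B genes among those higher. Genes with a serial number only again went the other way, with 191 higher and 319 lower. The 2 highest ratios were TRIAE_CS42_1DS_TGACv1_080991_AA0256470, with 2177 counts against 0 (at least 948-fold), and TRIAE_CS42_1BS_TGACv1_049356_AA0150030, with 1751 against 0 (at least 762-fold). Both are among the genes without a read in any library but N2_Cd. Without all genes seen in that library alone, 4221 genes were higher and 2464 lower. The lowest ratios were TRIAE_CS42_3AS_TGACv1_211337_AA0688740, with 0 counts against 4204 (at least 1073-fold lower), and TRIAE_CS42_1AS_TGACv1_020412_AA0077320, with 0 against 2437 (at least 622-fold lower). On log2(FPKM + 1) the balance was 3823 higher and 4047 lower. Across genes, the Cd ratios without Zn of the 2 Ca/K levels, which share no library, correlated at r = 0.58 (rho = 0.49). The Cd ratios with Zn did not go with them: N2_Cd_Zn against N2_Zn had r = 0.03 with the basal and 0.01 with the high pair, N0_Cd_Zn against N0_Zn had r = -0.23 and -0.29, and these 2 pairs had r = -0.35 with each other.

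Zn at basal Ca/K went with more genes lower than higher. In N0_Zn against N0, 2657 genes were higher and 3293 lower of 31538, and genes at 8-fold or more numbered 101 higher and 614 lower. Novel02379, a locus without an arm code, had 6547 counts against 5 (1385-fold, 593 to 4268), and TRIAE_CS42_4AL_TGACv1_289001_AA0963150 had 835 against 45 (19.6-fold, 14.5 to 27.1). TRIAE_CS42_2AL_TGACv1_096831_AA0321620 had 1 count against 1808 (1709-fold lower, 306 to 67540) and TRIAE_CS42_4AS_TGACv1_308683_AA1029050 had 2 against 1272 (601-fold lower, 166 to 4969). On log2(FPKM + 1) the split was 1708 higher and 4263 lower.

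At high Ca/K the large Zn changes again lay on the lower side, whereas the 2-fold balance did not. In N2_Zn against N2, 3172 genes were higher and 2301 lower of 32471, but 252 were 8-fold or more higher and 653 lower. The highest ratios were TRIAE_CS42_7BS_TGACv1_594052_AA1955780, with 473 counts against 0 (at least 207-fold), and TRIAE_CS42_5AL_TGACv1_376955_AA1242720, with 450 against 3 (197-fold, 67.1 to 960). The lowest were TRIAE_CS42_5BL_TGACv1_404270_AA1293200, with 2 counts against 3227 (1227-fold lower, 339 to 10130), and TRIAE_CS42_2BS_TGACv1_145847_AA0447090, with 0 against 1204 (at least 305-fold lower). On log2(FPKM + 1), without TMM scaling, the split turned to 2400 higher and 3692 lower, and the median log2 ratio from 0.065 to -0.16. A minimum of 1 CPM turned the split to 5597 and 6239, while size factors kept it at 3318 and 2204. The direction of the 2-fold balance was therefore not stable. The Zn ratios without Cd of the 2 Ca/K levels correlated across genes at r = 0.39 (rho = 0.26). N2_Cd_Zn against N2_Cd had r = 0.31 with the basal and 0.03 with the high pair, and N0_Cd_Zn against N0_Cd had r = -0.47 and -0.46.

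A small group of genes was lower with Zn in every matched pair. Over the 4 pairs that differ in Zn alone, 116 genes were 2-fold or more lower and 22 higher in all of them, against 25.7 in all expected from independent pairs. As many as 801 genes fitted the pattern with the N0_Cd_Zn pair turned, 442 with both pairs that contain Cd turned and 299 with the N2_Zn pair turned, so that the excess over 25.7 is not specific to a shared Zn effect. TRIAE_CS42_7AL_TGACv1_556472_AA1763730 averaged a log2 ratio of -7.65 ± 0.94 (SD over 4 pairs), and TRIAE_CS42_U_TGACv1_642434_AA2117550 averaged -8.31 ± 1.91. The latter was at 34.7 CPM in N0, 280 in N0_Cd, 931 in N2 and 586 in N2_Cd, and at 0.688, 0.400, 1.86 and 0.621 CPM in N0_Zn, N0_Cd_Zn, N2_Zn and N2_Cd_Zn. Among arms with at least 200 genes, 7AL and 7BL held the highest shares of these recurrent genes, with 12 lower and 1 higher of 1449 on 7AL (0.897%) and 8 lower and 4 higher of 1589 on 7BL (0.755%). These genes were chosen after their values were seen.

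**Figure D3:**
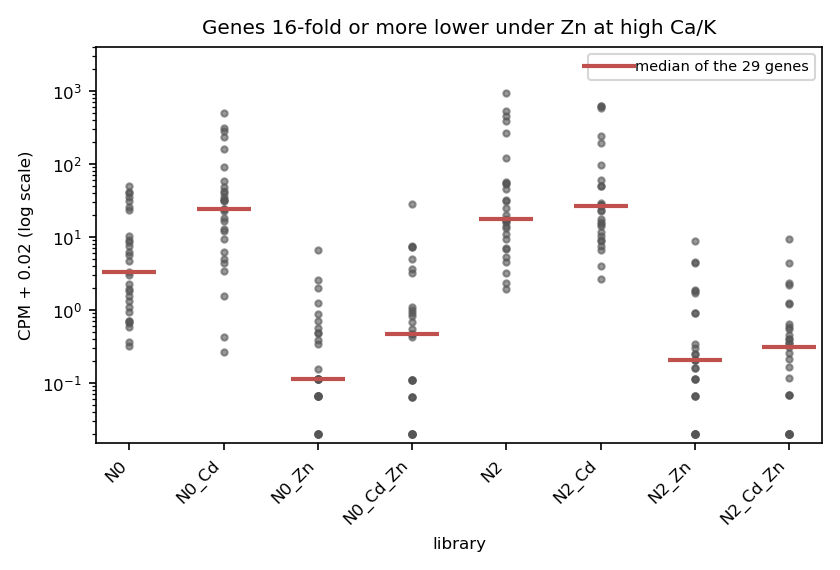
CPM plus 0.02 (log scale) of the 29 genes that were 16-fold or more lower with Zn in both matched pairs at high Ca/K and not 2-fold lower with Cd, in each of the 8 libraries; points are genes and red bars medians. The medians are 3.29 CPM in N0 and 24.2 in N0_Cd, against 0.0917 in N0_Zn and 0.445 in N0_Cd_Zn, with the 16-fold threshold set after basal values were seen.

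The tested effects of the metals did not pass correction. With edgeR's quasi-likelihood test on the additive model, 0 of 64580 genes were called for Cd, with 1918 at an unadjusted p under 0.05; DESeq2 called 347 (303 higher, 44 lower) and limma on FPKM 0. For Zn, edgeR called 0 genes with 1271 at an unadjusted p under 0.05, DESeq2 called 203 (39 higher, 164 lower), and limma on log2(FPKM + 1) called 1. Both unadjusted edgeR counts were a smaller share of the 64580 genes than the 0.05 that chance alone gives, so neither points to an effect. They also depended on single libraries. Leaving out 1 library gave 939 (without N0) to 6431 (without N0_Cd_Zn) for Cd. For Zn it gave 758 (without N2_Cd) to 8371 (without N0_Cd_Zn). The genes recurrently higher with Cd numbered 143 and those lower 23, against 25.3 in all expected from independent pairs, but 656 genes fitted with the N0_Cd_Zn pair turned, 383 with both pairs that contain Zn turned and 272 with the N2_Cd_Zn pair turned. TRIAE_CS42_5AL_TGACv1_374690_AA1206640 averaged 3.05 ± 0.79 (SD, 4 pairs) and TRIAE_CS42_5BL_TGACv1_404484_AA1301580 2.66 ± 0.48, and both were chosen after their values were seen. Without the pair that holds N0_Cd_Zn, 682 genes were higher and 420 lower with Cd in the other 3 pairs, and 411 higher and 855 lower with Zn. Without the pair that holds N2_Cd_Zn, 555 were higher and 450 lower with Cd, and 87 higher and 222 lower with Zn.

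Both metals together at basal Ca/K gave a profile unlike that of either metal. In N0_Cd_Zn against N0, 4262 genes were higher and 4669 lower of 32876, a balance that turned to 4499 and 4433 with size factors and 5105 and 4049 on log2(FPKM + 1). TRIAE_CS42_4BS_TGACv1_329042_AA1097330 had 1101 counts against 0 (at least 377-fold) and TRIAE_CS42_2AL_TGACv1_093231_AA0275620 had 3135 against 5 (644-fold, 276 to 1985). TRIAE_CS42_6BL_TGACv1_499782_AA1591600 had 1 count against 1232 (1199-fold lower, 215 to 47420) and TRIAE_CS42_1BL_TGACv1_031670_AA0118380 had 1 against 960 (935-fold lower, 167 to 36960).

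Against each single metal the combined basal library differed more. In N0_Cd_Zn against N0_Cd, 4628 genes were higher and 6657 lower of 34027, and against N0_Zn, 7166 were higher and 7841 lower of 33924, or 44.2% of the genes compared. TRIAE_CS42_4AL_TGACv1_288766_AA0957540 headed both comparisons, with 11737 counts against 0 in N0_Cd (at least 4261-fold) and against 4 in N0_Zn (2849-fold, 1112 to 10460). TRIAE_CS42_3B_TGACv1_223227_AA0778410 came next in both, with 14039 counts against 4 in N0_Cd (3823-fold, 1493 to 14030) and 6 in N0_Zn (2272-fold, 1043 to 6191). The genes furthest below N0_Cd were TRIAE_CS42_U_TGACv1_642434_AA2117550, with 9 counts against 6865 (700-fold lower, 369 to 1532), and TRIAE_CS42_1AS_TGACv1_021675_AA0082050, with 1 against 1503 (1380-fold lower, 247 to 54540). Those furthest below N0_Zn were Novel02379, with 3 counts against 6547 (2248-fold lower, 769 to 10900), and TRIAE_CS42_5AL_TGACv1_375389_AA1220900, with 3 against 824 (283-fold lower, 96.5 to 1375). On log2(FPKM + 1) the comparison with N0_Zn split into 10164 higher and 6106 lower genes.

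At high Ca/K both metals together gave a profile close to that of Zn. In N2_Cd_Zn against N2, 3848 genes were higher and 3519 lower of 32942, a balance that turned to 3196 and 4540 on log2(FPKM + 1). Novel06751 had 1123 counts against 0 (at least 506-fold) and TRIAE_CS42_3B_TGACv1_223027_AA0775410 had 2515 against 55 (61.8-fold, 47.3 to 82.3). TRIAE_CS42_U_TGACv1_642434_AA2117550 had 13 counts against 26338 (1499-fold lower, 876 to 2815), and TRIAE_CS42_7BS_TGACv1_592277_AA1934820 had 0 against 2472 (at least 610-fold lower).

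Against N2_Cd, N2_Cd_Zn had 2683 genes higher and 4365 lower of 32895. Novel09935 had 1203 counts against 0 (at least 415-fold) and Novel00557 had 1600 against 1 (1656-fold, 297 to 65460). The 2 lowest ratios were the genes of arms 1DS and 1BS named above that had reads in N2_Cd alone, with 0 counts against 2177 and 1751 (at least 701-fold and 564-fold lower). Against N2_Zn, 1943 genes were higher and 2690 lower of 31873, or 14.5%, which turned to 2304 and 2076 on log2(FPKM + 1). TRIAE_CS42_5AL_TGACv1_374914_AA1211820 had 1232 counts against 5 (253-fold, 108 to 782) and TRIAE_CS42_7AS_TGACv1_569206_AA1810290 had 463 against 2 (238-fold, 65.5 to 1971). TRIAE_CS42_7AL_TGACv1_557853_AA1787110 had 18 against 2521 (136-fold lower, 86.03 to 230.3) and TRIAE_CS42_5AL_TGACv1_374997_AA1213670 had 3 against 550 (178-fold lower, 60.7 to 868).

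The medians of genes that differed with metal at high Ca/K went the same way at basal Ca/K with Cd or Zn, and the other way with both. The 1705 genes 2-fold or more higher than N2 in all 3 metal libraries of high Ca/K had a median log2 ratio of 1.15 in N0_Cd, 0.61 in N0_Zn and -0.91 in N0_Cd_Zn, each against N0. The 1986 genes lower in all 3 had medians of -1.79, -2.17 and 0.90. Not every gene followed: 943 of the 1705 genes were 2-fold higher in N0_Cd and 575 in N0_Zn, and in N0_Cd_Zn 793 were lower and 222 higher. Of the 1986 genes, 1355 were 2-fold lower in N0_Cd and 1451 in N0_Zn, and in N0_Cd_Zn 957 were higher and 189 lower. The medians of 10000 random lists of the 1705 genes' size lay between -0.19 and 0.02 for N0_Cd_Zn, and those for the 1986 genes between -0.11 and 0.12. No library is shared between the choice of these genes and the values given. In the reverse direction, the 2085 genes higher than N0 in both N0_Cd and N0_Zn had medians of 0.80, 0.41 and 0.87 in N2_Cd, N2_Zn and N2_Cd_Zn against N2, and the 2605 genes lower had -1.60, -1.45 and -1.55. TRIAE_CS42_6BL_TGACv1_501070_AA1613150, among the lower genes fixed at high Ca/K, had 16.4 CPM in N0 and 15.4 in N0_Cd_Zn but 0.163 in N0_Cd and 0.688 in N0_Zn, and it was chosen after its values were seen.

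**Figure D4:**
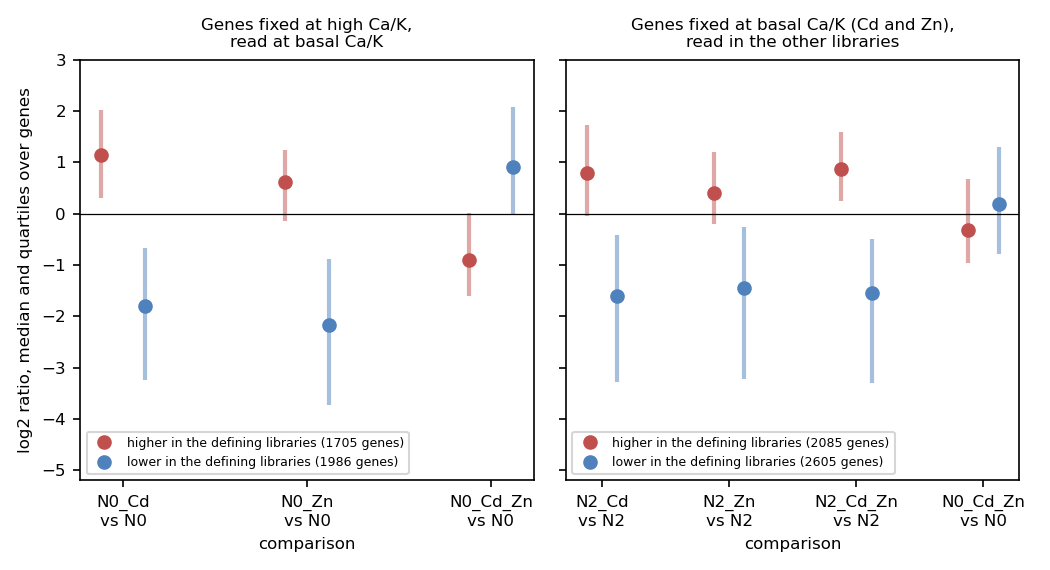
Log2 ratio to the untreated library (median as point, quartiles as line, over genes) of genes higher (red) or lower (blue) with metal. The comparison is on the horizontal axis. Genes were fixed at the other Ca/K level, except that the right panel also reads the genes fixed at basal Ca/K in N0_Cd_Zn against N0. That comparison shares the N0 library with their choice. In the left panel the red median is 1.15 in N0_Cd and -0.91 in N0_Cd_Zn, and the blue median is -1.79 and 0.90.

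The raised Ca/K supply without metal went with many genes in each direction. In N2 against N0, 4574 genes were higher and 5262 lower of 33354, which turned to 6383 and 3861 on log2(FPKM + 1). Novel02379 had 1222 counts against 5 (200-fold, 85.2 to 615), and TRIAE_CS42_4AL_TGACv1_291993_AA0997320 had 2894 against 16 (148-fold, 90.8 to 259). Novel06751 had 0 counts against 2939 (at least 1200-fold lower), and TRIAE_CS42_3AL_TGACv1_194953_AA0642620 had 6 against 3541 (723-fold lower, 332 to 1972).

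Under Cd the Ca/K levels differed least. In N2_Cd against N0_Cd, 3555 genes were higher and 3628 lower of 32993, which turned to 3688 and 3420 on log2(FPKM + 1). The 2 highest ratios were again the 1DS and 1BS genes with reads in N2_Cd alone, with 2177 and 1751 counts against 0 (at least 820-fold and 660-fold). Novel00557 had 1 count against 1491 (1319-fold lower, 236 to 52130) and Novel09935 had 0 against 757 (at least 223-fold lower). Without genes seen in N2_Cd alone, 3518 were higher and 3628 lower.

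Under Zn the Ca/K levels differed in 42.4% of genes. In N2_Zn against N0_Zn, 7267 genes were higher and 6888 lower of 33385, and on log2(FPKM + 1) 9164 were higher and 5188 lower. TRIAE_CS42_4BL_TGACv1_321485_AA1061230 and TRIAE_CS42_4BL_TGACv1_321657_AA1063720 had 1258 and 1203 counts against 0 (at least 426-fold and 407-fold). TRIAE_CS42_5AL_TGACv1_374914_AA1211800 and TRIAE_CS42_5AL_TGACv1_374914_AA1211820, on the same scaffold, had 0 against 3808 (at least 1251-fold lower) and 5 against 6599 (1301-fold lower, 557 to 4007).

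Under both metals the Ca/K levels differed in 38.3% of genes. In N2_Cd_Zn against N0_Cd_Zn, 6828 genes were higher and 6330 lower of 34372. Novel04906 had 1150 counts against 0 (at least 412-fold) and TRIAE_CS42_6DL_TGACv1_526452_AA1684100 had 1116 against 1 (1199-fold, 215 to 47400). TRIAE_CS42_4AS_TGACv1_308683_AA1029050 had 1 against 5738 (5341-fold lower, 958 to 211000) and TRIAE_CS42_3AS_TGACv1_211826_AA0694730 had 0 against 3262 (at least 1012-fold lower).

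Across the 4 Ca/K pairs, 1 gene passed the test. TRIAE_CS42_2AS_TGACv1_112986_AA0349180 was lower at high Ca/K, with an edgeR log2 fold change of -6.12 (SE 0.33), an unadjusted p of 7.11e-07 and an adjusted p of 0.0459, and lower in all 4 pairs. It had 894, 349, 895 and 549 counts in N0, N0_Cd, N0_Zn and N0_Cd_Zn and 20, 6, 10 and 5 in N2, N2_Cd, N2_Zn and N2_Cd_Zn. Of 64580 genes, 10574 had an unadjusted p under 0.05, and DESeq2 called 6482 genes (3236 higher, 3246 lower) and limma on log2(FPKM + 1) 650 (416 higher, 234 lower). Leaving out N0_Cd_Zn raised edgeR's calls to 3594 (1123 higher, 2471 lower), whereas leaving out any of the other libraries, or adding the Cd by Zn term, gave 0.

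Many more genes differed in the same direction in all 4 Ca/K pairs than for either metal. Of 51428 genes, 1226 were 2-fold or more higher and 707 lower in every pair, against 71.7 in all expected from independent pairs. The share was alike on the A subgenome (503 higher, 272 lower, 3.98%) and the B subgenome (562 higher, 283 lower, 4.15%). TRIAE_CS42_7BL_TGACv1_577121_AA1866510 averaged 5.34 ± 1.09 (SD of the log2 ratio, 4 pairs) and TRIAE_CS42_2BS_TGACv1_146323_AA0462570 averaged -6.37 ± 0.82, both chosen after their values were seen. The Ca/K ratios of the pairs without metal, with Cd and with Zn correlated across genes at r between 0.54 and 0.65 (rho between 0.56 and 0.67). Each correlated with the pair of both metals at r between 0.07 and 0.11 (rho between -0.01 and 0.05). Without that last pair, 2602 genes were higher and 2802 lower in the other 3.

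The library with both metals departed from the sum of the single-metal changes more widely at basal Ca/K. Each departure rests on single libraries, so it cannot separate joint action of the metals from library noise or a wrong label. The log2 departure from additivity had an SD across 51428 genes of 2.33 at basal and 1.48 at high Ca/K, and 49.4% and 32.7% of genes departed 2-fold or more. Departures at the 2 levels correlated across genes at r = 0.26 (rho = 0.06). The Cd by Zn interaction averaged over Ca/K levels had 0 edgeR calls of 64580 genes, with 4920 at an unadjusted p under 0.05; DESeq2 called 1453 (1213 higher, 240 lower) and limma on FPKM 0. Leaving out any library leaves a combination of Cd and Zn with a single library. Such a refit measures no recurrence over libraries. Its calls are therefore listed only among the processing alternatives, and no conclusion is drawn from them.

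The change of each metal's effect with Ca/K was also tested. The Cd by Ca/K interaction had 0 edgeR calls with 2487 genes at an unadjusted p under 0.05, 247 DESeq2 calls (85 higher, 162 lower) and 0 limma calls on FPKM. The Zn by Ca/K interaction had 0 edgeR calls with 945 genes at an unadjusted p under 0.05, 123 DESeq2 calls (28 higher, 95 lower) and 0 limma calls. Both unadjusted counts were a smaller share of the genes than the 0.05 that chance alone gives. Here too, leaving out any library leaves a combination of factors with a single library. No conclusion is drawn from the calls of such refits, which are listed only among the processing alternatives. Of 100 simulated 16-fold Cd by Zn interactions, 0 were recovered at the dispersions fitted by the additive model. Their common value was 0.368, against 0.281 in the model with this interaction, so the simulation was noisier than the test. The 0 calls do not exclude such changes, and the other 2 interactions were not simulated.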

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

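All tests in this part were chosen after the results were seen, and the comparison of gene sets between Ca/K levels was too. N2_Cd had reads on 13525 genes with a D code, far from the next library at 11647, and 132 genes with at least 10 reads and none elsewhere, far from the next at 21. These were 2 of 16 library measures whose gap exceeded Dixon's 95% critical value over the 8 libraries taken as 1 group; chance alone exceeds it in about 1 in 20 measures. The genes higher with Cd and with Zn at basal Ca/K had a median log2 ratio of -0.31 in N0_Cd_Zn against N0 but 0.87 in N2_Cd_Zn against N2, and the genes lower had 0.19 (0.0087 on log2(FPKM + 1)) against -1.55. The opposite directions in the 2 Ca/K levels were not tested, since each rests on 1 library, and the N0 library shared with the choice of genes by itself pulls the first value of each pair the other way.

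The library labelled N0_Cd_Zn ran opposite to the metal response, as the plot of set medians shows. A trend on gene length and mean expression is not its whole cause, because removing both trends left the sets fixed at high Ca/K at -0.82 (95% bootstrap interval over genes -0.87 to -0.75) and 0.81 (0.72 to 0.87). Plants that had received no added Zn cannot be excluded: the 174 genes 4-fold lower with Zn at high Ca/K went both ways in N0_Cd_Zn against N0 (median -0.25, 69 genes 2-fold lower, 50 higher; -1.17 over 62 genes on log2(FPKM + 1)) and the 121 genes higher with Zn were at -0.77 (0.37 over 60 genes on log2(FPKM + 1)), whereas the 29 genes at 16-fold, a threshold set after those values were seen, were at -3.42 (quartiles -4.15 to -2.32). Plants that had received no Cd cannot be told apart from Zn countering Cd at basal Ca/K. The 161 genes 4-fold higher with Cd at high Ca/K, and not 2-fold higher in N2_Zn against N2, had a median of -0.25 against N0. Against N0_Zn their median was -0.61 (71 genes 2-fold lower, 40 higher). Both readings put these genes no higher than in N0_Zn, but neither by itself puts them below it. The 36 genes 4-fold lower with Cd went both ways against N0 (median -0.99, 18 genes 2-fold lower, 11 higher) and were at 0.97 against N0_Zn. They were also at -2.66 in N0_Zn against N0, so that they do not single out Cd. A lessened Cd response in the presence of Zn at basal Ca/K may therefore be treated as a hypothesis for new plants, not as a finding.

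The recurrence of Ca/K differences over 4 pairs was compared with chance and with exchanged labels. Among 33 splits of the 8 libraries, 2, the Ca/K split included, gave at least its number of genes at an unadjusted p under 0.05 (10574, highest other 10959), so chance cannot be excluded by this count, though that other split only exchanged N0_Cd_Zn and N2_Cd_Zn and kept 6 libraries on their Ca/K side. A first test of such an exchange, the genes 2-fold apart in all pairs with the pair of both metals turned (1147, against 1933 as labelled), could not tell, and the medians that follow were taken in its place after that result was seen. In the genes that differed in the other 3 pairs, the pair of both metals had a median of 0.77 over the 2602 higher genes (1226 the same way, 658 opposite) and -0.22 over the 2802 lower genes (707 and 489, quartiles -1.01 to 0.62). An exchange would turn the signs, so these medians argue against it, weakly for the lower genes. Over all 51428 genes the rank correlation of that pair with each of the others lay between -0.01 and 0.05, which points neither way. Removing trends on length and expression left 1863 genes of 1933, and whether the genes follow Ca, K or the nitrate that rose with them was not tested.

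The genes seen in N2_Cd alone may come from reads of another wheat. Of the 132 genes, 58.3% had a D code (95% Wilson interval 49.8% to 66.4%), against 28.4% of all genes in the table and 19.7% of those detected in any library; 17 of them on the short arms 1AS, 1BS and 1DS held 57.2% of the reads, as 2 of 15 such genes in N2 held 34.3%, and the origin of this was not tested. A carry-over of hexaploid wheat material into this library is a candidate explanation that this share goes with. Deeper sequencing is argued against, since 5 libraries had higher totals. The 44 A and B genes among them could also be genes switched on by Cd at high Ca/K, which cannot be told apart from carry-over because a hexaploid wheat has the same subgenomes.

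For the other tested effects chance cannot be excluded either, and the splits are no clean measure of it. The splits for each interaction include the other interactions, and some splits repeat the same fit. With the real split included, as many genes at an unadjusted p under 0.05 came from 15 of 33 splits for Cd (1918, highest other 11117), 21 of 33 for Zn (1271, highest other 15286), 8 of 32 for Cd by Zn (4920), 11 of 32 for Cd by Ca/K (2487) and 24 of 32 for Zn by Ca/K (945), with a highest other of 15249 in all 3 interactions. That highest other split set N0, N0_Cd_Zn, N2 and N2_Zn against the rest and, with the 3 factors in the model, called 1151 genes. It was picked for its count, and interactions of the 3 factors can form it, so no structure beyond them is shown.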

How the results depend on the processing

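The recurrence counts, gene sets, marker genes and removal of genes seen in N2_Cd alone were alternatives or results chosen after seeing the data; the others were fixed beforehand. By replicate, no paired analysis was possible because the columns carry no replicate numbers, and gene list tests were not run because identifiers lack names. Size factors in place of TMM and no filter on low counts left all 6 tested effects on their side of the threshold. DESeq2 called 347 genes for Cd, 203 for Zn, 6482 for Ca/K, 1453 for Cd by Zn, 247 for Cd by Ca/K and 123 for Zn by Ca/K, where edgeR called 0, 0, 1, 0, 0 and 0; the cause was not tested. With limma on log2(FPKM + 1) and log2(FPKM + 0.1), Ca/K had 650 and 643 calls and Zn 1 and 1. Adding the Cd by Zn term, which compares the Ca/K levels within each metal treatment, left Ca/K with 0. For each interaction, leaving out any library leaves a combination of factors with a single library. Interaction calls of such refits measure no recurrence over libraries, so they are listed only for completeness and no conclusion is drawn from them. Leaving out each library in turn gave 0 to 3594 calls for Ca/K (3594 without N0_Cd_Zn), 0 to 3469 for Cd by Zn (3469 without N2_Cd_Zn), 0 to 21 for Zn by Ca/K (21 without N0_Zn), and 0 throughout for Cd, Zn and Cd by Ca/K.

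A minimum of 1 CPM in place of 5 admits more genes and raised the number 2-fold apart in all 14 pairwise comparisons: to 13800 in N0_Cd vs N0, 12550 in N0_Zn vs N0, 16566 in N0_Cd_Zn vs N0, 20760 in N0_Cd_Zn vs N0_Cd, 25514 in N0_Cd_Zn vs N0_Zn, 14076 in N2_Cd vs N2, 11836 in N2_Zn vs N2, 14403 in N2_Cd_Zn vs N2, 13414 in N2_Cd_Zn vs N2_Cd, 9519 in N2_Cd_Zn vs N2_Zn, 17215 in N2 vs N0, 12812 in N2_Cd vs N0_Cd, 22810 in N2_Zn vs N0_Zn and 23488 in N2_Cd_Zn vs N0_Cd_Zn. The totals of the other 45 alternatives stayed within 1.5 times, but on log2(FPKM + 1) the lower genes went from 2464 to 4047 in N2_Cd vs N2 and from 2301 to 3692 in N2_Zn vs N2, and the higher genes from 2657 to 1708 in N0_Zn vs N0. The 70 alternatives of set medians kept their sign, 41 of them within the bootstrap interval. On log2(FPKM + 1) several shrank: in N0_Cd_Zn against N0 the higher genes fixed at high Ca/K to -0.42, the lower genes fixed at basal Ca/K to 0.0087, the higher genes fixed at basal Ca/K to -0.19, and the lower genes fixed at high Ca/K to -0.98 in N0_Cd and -1.21 in N0_Zn. Against N2 the higher genes fixed at basal Ca/K went to 0.47 in N2_Cd and 0.25 in N2_Zn. With a mean of at least 5 CPM the genes fixed at basal Ca/K were at -0.50 and 0.12 in N0_Cd_Zn against N0. On log2(FPKM + 1), recurrent genes numbered 41 for Cd, 60 for Zn and 1009 for Ca/K, against 166, 138 and 1933. Among genes with a mean of at least 5 CPM they numbered 58, 70 and 1065. Of 20 alternatives for the marker genes in N0_Cd_Zn against N0, 3 turned sign: the 4-fold Zn-lower genes to 0.022 with A and B genes only, and the Zn-higher and Cd-lower genes to 0.37 and 0.18 on log2(FPKM + 1); the cause was not tested. On that scale the 4-fold Zn-lower genes went the other way, from -0.25 to -1.17, and the 16-fold ones were at -1.98. Counts of 1 to 3 in 1 library limit the precision of the largest ratios, as their intervals show.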

Other observations

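The results of this part were chosen after the data were seen. Part of the genes that were far lower with Zn at high Ca/K were higher with Cd at basal Ca/K. Of 294 genes 4-fold lower with Zn in both high Ca/K pairs, 112 were 2-fold higher and 96 lower in N0_Cd against N0 (median log2 ratio 0.18). Over the 174 of them not 2-fold lower with Cd at high Ca/K, a filter that itself favours higher values, the median was 1.26, with 100 genes higher and 19 lower, above all of 10000 random lists drawn with the same filter and matched on expression and on the Cd ratio at high Ca/K (highest 0.50). At 16-fold, a threshold set after the values were seen, the median was 2.69 over 39 genes without the filter (27 higher, 7 lower) and 2.99 over the 29 genes with it (24 higher, 2 lower; highest random median 0.71). Of these 29 genes, 6 lay on arm 7AL, which holds 1449 of the 51428 genes, 3 on 2AL and 7 had no arm code. The 7AL genes include neighbours on the same scaffolds, which can share reads and are not independent. The median of all 29 genes was 3.29 CPM in N0, 24.2 in N0_Cd, 17.8 in N2 and 26.9 in N2_Cd. The choice of these genes itself asks for high values in N2 and N2_Cd, so a lower median in N0 than in those libraries is largely built in. N0 and N0_Cd were not in the ratios that chose the genes. TRIAE_CS42_6AL_TGACv1_471892_AA1515680 had 30.8 CPM in N0, 498 in N0_Cd, 451 in N2 and 619 in N2_Cd, and between 1.07 and 2.52 in the libraries with Zn.

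Genes higher with Zn alone did not clearly show the reverse. The 121 genes 4-fold higher with Zn in both high Ca/K pairs and not 2-fold higher with Cd there had a median of -0.32 in N0_Cd against N0 (37 genes 2-fold higher, 46 lower), which was 0.63 on log2(FPKM + 1). They were at 1.32 in N0_Zn against N0 (70 higher, 8 lower) and at -0.77 in N0_Cd_Zn against N0 (34 higher, 55 lower), the latter turning to 0.37 on log2(FPKM + 1). The 161 genes 4-fold higher with Cd were so in both high Ca/K pairs and were not 2-fold higher in N2_Zn against N2. Their median was 1.65 in N0_Cd against N0 (100 higher, 12 lower) and 0.07 in N0_Zn (39 higher, 21 lower). The filter on the Zn ratio by itself favours lower values in N0_Zn.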
